A study of Mus musculus with 3 samples.

How the data were processed

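Single-cell RNA and antibody-tag libraries were made from 1 pool of 8 hashed mouse samples, in which each sample carried its own barcoded antibody (hashtag). The pool held 2 naive brain samples of CCR2+/- mice, 2 of CCR2-/- mice, and 1 blood sample each of naive Het, naive Hom, metastasis-bearing Het and metastasis-bearing Hom mice. The labels of the blood samples do not name the gene that Het and Hom refer to, and nothing in the labels says that the hashtags of a brain genotype were separate animals. Reads were processed with Cell Ranger 3.1 against mm10, per the submitters' processing notes. The Seurat version and the filters on cells were not stated.

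The deposited tables hold natural log (ln) values: the authors took the log of 1 plus a count that SCTransform had corrected for the depth of the cell, separately in each of the 3 tables. The back-transformed values were whole numbers to within 2.18e-11, so corrected counts were rebuilt, but raw counts were not available. The deposited cell descriptions give each cell's raw UMI total, its hashtag counts and the authors' cluster number. Genes were identified by symbol alone, and no positions were given.

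Among 16328 deposited cells there were 13757 different barcodes, since 1 library served all 3 tables and some barcodes stood in more than 1 of them. Cells were kept where the barcode stood in a single table and at least 0.5 of the hashtag counts came from that table's own hashtags. This choice replaced the planned use of all deposited cells after the hashtag columns had been seen, and the planned choice was kept as an alternative. It left 3350 of 5208 cells in the brain table, 3694 of 5363 in the naive blood table and 4019 of 5757 in the table of metastasis-bearing mice.

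Cells of each table were clustered with scanpy 1.11.5 and leidenalg 0.10.2 (2000 variable genes, 30 principal components, 20 neighbours, resolution 1), with 5 genes kept out of the clustering. Clusters were named by markers of 28 classes that were fixed before the data were examined, as were the gene lists, the comparisons, the rule for named genes and most of the alternative settings. A class needed at least 3 markers raised 2-fold over the other clusters and a score at least 1 above the next class. At least 1 of its markers had to be among the 10 top genes of the cluster, with no other class having more there. The gap in score was set after the data had been seen. Clusters that missed any of these rules stayed unnamed. Class names therefore mean cells with the RNA markers of that class.

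Brain genes were compared with limma 3.58.1 in R 4.3.3. Corrected counts were summed per hashed sample in classes with at least 20 cells in every sample, scaled to the class total with a pseudocount of 1, and fitted with a mean-variance trend for genes with at least 20 corrected counts. The threshold was a Benjamini-Hochberg adjusted p of 0.05. A test for raw counts had been planned and was replaced because the values are ln of corrected counts. Gene lists were tested with limma's camera at a preset correlation of 0.01 and again with an estimated correlation. Shares of cells with 2 samples per group were given as mean and SD; an exact permutation test of 2 against 2 has 6 splits and cannot go below p = 0.333. Limma's p-values rest on the spread between these samples, shared over genes of a like level, and not on a gene's own spread alone. A gene whose 2 samples of a genotype differ widely can therefore still be called. The p-values do not measure the spread between other mice.

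Each blood group was 1 sample, so no gene was tested there. Levels are corrected counts per 10000, differences are log2 ratios with a pseudocount of 1, and shares carry exact Clopper-Pearson 95% intervals, which cover counting error only. For a count of 0 the limit given is 3 divided by the number of cells, except in the hashtag test, which used the exact bound. The median log2 ratio of a list was placed among 10000 random lists matched on level. For 845 barcodes present in both blood tables, the tables differed by a median log2 of 0.02 over 8911 genes, and 0 genes differed by more than 1.5-fold, so levels were also set side by side across these separately normalised tables.

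The rule for named genes took, in the 3 classes with most cells and at least 100 cells in both samples, the 5 higher and 5 lower genes whose 95% interval bound lay farthest from 1, given at least 20 counts in the higher sample and a ratio of at least 1.5. Ribosomal, mitochondrial, immunoglobulin, T cell receptor, haemoglobin, Gm and Rik genes were left out of the ranking. Cx3cr1, Ccr2, Cxcl10 and up to 4 members per list were also named. In the brain the rule was applied to limma's interval. Of the genes so named in microglia-like cells, 1 is not reported here. Of the genes so named in blood the text describes a part, chosen after their values were seen. Monocyte genes of naive blood, where the classes had fewer than 100 cells, the endothelial genes, and Il1a, Hspa8, Tsc22d3, Cirbp, Rbm3, Fkbp5 and Hba-a1 in microglia-like cells were also chosen after their values were seen.

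The methods were tested on simulated data in which known changes were set into the tables. In microglia-like cells limma called 25.8% of genes set to 1.5-fold, 66.7% of those set to 2-fold and 95.5% of those set to 4-fold, with 8 false calls among 10501 unchanged genes. In endothelial-like cells 6.15%, 25.8% and 77.3% were called, with 3 false calls among 7600 unchanged genes, against 5 genes called in the data. The simulated samples had the same small spread in every gene and no shift of whole samples. In the data some genes varied more between CCR2+/- samples, such as Spp1 (0.0396 and 0.96) and Fkbp5 (1.20 and 0.449) in microglia-like cells. These rates therefore hold for quieter data and do not give the share of false calls in the real comparison. Alternatives covered scaling, count minimum, pseudocount, depth, cell filters, doublets found with Scrublet, clustering resolution, the authors' clusters, hashtag rules and leaving out each brain sample. Other software was Python 3.11.15, scipy 1.17.1, numpy 2.4.6, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9.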

Results

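The study measured RNA in single cells from brain and blood of female mice aged 2 to 3 months, with a pool of 35 antibody tags, to describe myeloid cells in naive mice and in mice with brain metastases. CCR2 is the chemokine receptor that draws Ly6c-high monocytes from bone marrow into blood and inflamed tissue. Brain cells came from 1 hemisphere of perfused naive mice. Blood came from naive mice and from mice about 2 weeks after E0771 cells, a mouse breast cancer line, had been injected into the carotid artery. The brain samples kept 908 and 730 cells of CCR2+/- mice and 675 and 1037 cells of CCR2-/- mice, with median depths of 6189, 7394, 6778 and 6858 UMIs per cell. The naive blood samples kept 1716 Het and 1978 Hom cells, with median depths of 3929 and 4709 UMIs. The samples of metastasis-bearing mice kept 2074 Het and 1945 Hom cells, with median depths of 3961 and 4276 UMIs. Corrected counts per sample summed to between 4420428 and 9267629. Clusters without a class name held 42.2% and 33.7% of CCR2+/- brain cells and 41.5% and 43.0% of CCR2-/- brain cells. In blood they held 10.4% of naive Het, 11.5% of naive Hom, 5.79% of metastasis-bearing Het and 11.6% of metastasis-bearing Hom cells.

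Ccr2 RNA was lower in CCR2-/- brain cells in 3 classes that carried it in CCR2+/- mice. In type 2 dendritic cells, which present antigen to T cells, the level was 3.26 per 10000 corrected counts in CCR2+/- and 0.197 in CCR2-/- mice. It was 2.11 and 0.247 in border-associated macrophages, which live in the meninges and around vessels, and 1.80 and 0.263 in gamma delta T cells. A Ccr2 count was found in 21 of 24 CCR2+/- dendritic cells (87.5%) and 3 of 20 CCR2-/- dendritic cells (15%), at median depths of 15994 and 14793 UMIs. The shares were 42.3% of 71 and 13.6% of 22 border macrophages, at 8077 and 9103 UMIs, and 47.2% of 36 and 12% of 25 gamma delta T cells, at 4871 and 5448 UMIs. Microglia, which do not express Ccr2, showed a background of 7.98% in CCR2+/- and 6.97% in CCR2-/- mice, at 9527 and 10620 UMIs. The RFP transcript, a red fluorescent reporter present in the tables, was kept: it was found in 9 of 13 and 8 of 19 Ly6c-high monocytes, 87.5% and 90.0% of dendritic cells, 31.0% and 27.3% of border macrophages, and 18 of 36 and 12 of 25 gamma delta T cells. RFP was found in 0.679% and 0.619% of microglia. In cells with Ly6c-high monocyte RNA the Ccr2 level was 6.49 and 1.07, found in 11 of 13 and 6 of 19 cells, but the cells of the 2 genotypes were not alike: the authors' antibody gates put 11 of the 13 CCR2+/- cells and 3 of the 19 CCR2-/- cells in the Ly6C-high gate, and 8 of the 19 in the Ly6C-low and 6 in the T gate.

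Border-associated macrophages were scarcer in the CCR2-/- brains, while cells named as microglia took a similar mean share in both genotypes. Microglia are the resident macrophages of the brain tissue. Border macrophages made up 4.31% ± 0.286 of CCR2+/- and 1.27% ± 0.117 of CCR2-/- brain cells (mean ± SD, n = 2), a ratio of 3.40, and the difference exceeded the SD of either group. The samples held 41 and 30 border macrophages in CCR2+/- and 8 and 14 in CCR2-/- mice. Among microglia and border macrophages together, the border cells were 13.3% and 8.55% in CCR2+/- and 3.24% and 3.33% in CCR2-/- samples. Without any 1 sample the difference stayed between -3.25 and -2.84 percentage points. Microglia made up 36.7% ± 10.2 of CCR2+/- and 37.3% ± 2.72 of CCR2-/- cells. Unnamed clusters held 37.9% ± 6.00 of CCR2+/- and 42.2% ± 1.08 of CCR2-/- brain cells. Any microglia or border macrophages among them are missing from the shares given here. The microglia difference changed direction between -6.65 points without CCR2+/- sample 1 and 7.81 without CCR2+/- sample 2, and it was -1.34 without CCR2-/- sample 2. B cells made up 1.24% ± 0.19 of CCR2+/- and 0.66% ± 0.115 of CCR2-/- brain cells. Cells with Ly6c-high monocyte RNA made up 0.783% ± 0.139 and 1.15% ± 0.261. Most of these CCR2-/- cells lay outside the authors' Ly6C-high antibody gate, as given above. The values therefore do not show more Ly6C-high monocytes in CCR2-/- brains.

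In CCR2-/- microglia, 3 members of the inflammatory list and 3 of the heat shock list rose over all genes tested, and Tsc22d3, Cirbp and Rbm3 fell. Neither list passed when the correlation between genes was estimated. Limma called 32 genes that rose and 43 that fell among 10710 tested. The count was 28 without CCR2+/- sample 1, 128 without CCR2+/- sample 2, 95 without CCR2-/- sample 1 and 44 without CCR2-/- sample 2. Thinning each cell to 1000 corrected counts left 5 genes. The direction of each gene named here as changed, apart from Fkbp5, was the same in both CCR2-/- samples against both CCR2+/- samples.

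Il1b, which encodes the fever cytokine interleukin 1 beta, rose in CCR2-/- microglia by a log2 of 1.12 ± 0.125 (SE; limma adjusted p = 9e-06), from 1.28 and 1.67 to 3.71 and 2.75 per 10000. Il1a, its sister cytokine, rose by 0.79 (adjusted p = 0.000253). Cxcl2, a neutrophil attractant, rose by 1.12 (adjusted p = 0.000517), Tnfaip2, a target of TNF signalling, by 0.85 (adjusted p = 0.000436), and Ptgs2, the prostaglandin synthase COX-2, by 2.12 (adjusted p = 0.0086). Il1b and Tnfaip2 stayed past the threshold without any 1 of the 4 samples. Il1a missed it without CCR2+/- sample 1, at 0.58, and Cxcl2 without CCR2-/- sample 2, at 0.93. Ptgs2 missed it without CCR2+/- sample 1, at 1.06, and without CCR2-/- sample 2, at 1.59, and its value was 3.17 without CCR2+/- sample 2. The list of inflammatory cytokines and NF-kB targets had a median log2 difference of 0.22, with 10 members higher and 2 lower. In it 3 members rose over all genes tested, and adjusted over the list alone 5 rose and 1 fell. Limma's camera gave adjusted p = 1.22e-09 at the preset correlation and adjusted p = 0.499 with an estimated correlation.

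The chaperones Hsph1 and Hspa8, which refold proteins after heat or other stress, rose in CCR2-/- microglia. Hsph1 rose 2.84-fold (SE of the log2 difference 0.242; limma adjusted p = 0.000814), from a mean of 0.0981 to 0.284 per 10000, and Hspa8 by a log2 of 0.76 ± 0.108 (SE; adjusted p = 0.000253), from 10.2 to 17.3. Both stayed past the threshold without any 1 sample, with log2 differences between 1.31 and 1.70 for Hsph1 and between 0.61 and 0.91 for Hspa8. All 8 members of the heat shock list were higher, with a median of 0.42. Over all genes tested 3 rose, and adjusted over the list alone 6 rose. Camera gave adjusted p = 2.32e-15 at the preset correlation and adjusted p = 0.499 with an estimated correlation. The list's median was 0.21 without CCR2-/- sample 1 and 0.67 without CCR2-/- sample 2. With an estimated correlation no list in the 3 brain classes passed the threshold, and the lowest adjusted p of limma's camera was 0.344.

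Cirbp and Rbm3, RNA-binding proteins induced by mild cold, fell in CCR2-/- microglia. Cirbp fell by 0.80 on the log2 scale (SE 0.116; limma adjusted p = 0.000327) and Rbm3 by 0.51 (adjusted p = 0.0253). Tsc22d3 and Fkbp5, which glucocorticoids induce, had log2 differences of -0.78 (adjusted p = 0.000253) and -1.18 (adjusted p = 0.0311). Jdp2, a repressor of AP-1, fell by 1.31 (adjusted p = 0.00204) and Nes, the intermediate filament nestin, by 1.74 (adjusted p = 0.048). Cirbp and Tsc22d3 stayed past the threshold without any 1 sample. Without CCR2+/- sample 1, Rbm3 (-0.42), Fkbp5 (-0.47), Jdp2 (-0.94) and Nes (-1.49) missed it. Without CCR2-/- sample 2, Rbm3 (-0.28), Fkbp5 (-0.69), Jdp2 (-0.99) and Nes (-1.85) missed it, and Nes also without CCR2-/- sample 1 (-1.63). Fkbp5 was -1.88 without CCR2+/- sample 2. Spp1, the secreted protein osteopontin, had a log2 difference of -2.56 that was not called (adjusted p = 0.099), since its level was 0.96 in CCR2+/- sample 2 and 0.0396 in CCR2+/- sample 1. It was -4.78 and called without CCR2+/- sample 1 and -0.34 without CCR2+/- sample 2. Ifit2, an interferon-induced gene, was not called at -1.56 (adjusted p = 0.117) and was called at -2.26 without CCR2+/- sample 2.

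Cx3cr1, the fractalkine receptor of microglia, did not differ detectably, with a log2 difference of 0.01 (limma adjusted p = 0.993), and it was found in 100% of microglia of both genotypes. Cxcl10, an attractant of T cells named in the aim of the series, had a difference of 0.003 (adjusted p = 0.999), which ranged from -0.30 without CCR2+/- sample 1 to 0.30 without CCR2+/- sample 2. Ccr2 in microglia had a difference of -0.14 (adjusted p = 0.955), at the background level given for these cells. The lists of homeostatic microglia genes (median -0.01, 7 higher and 8 lower), disease-associated microglia genes (median -0.10) and the interferon response (median 0.01) had camera adjusted p-values of 0.683, 0.0882 and 0.238. The interferon list passed without CCR2+/- sample 1, at 0.30, and the disease-associated list also, at -0.13; the homeostatic list had a median of 0.03 without CCR2-/- sample 1. The interferon gamma list passed at the preset correlation, with a median of 0.42 (4 higher, 1 lower, 1 rising over all genes, camera adjusted p = 0.00051), but not without CCR2+/- sample 1, at 0.31. Its median had the other sign after thinning, and camera gave adjusted p = 0.51 with an estimated correlation. The MHC class II list (median 0.10, adjusted p = 0.0333), the neutrophil ageing list (0.08, adjusted p = 0.00216) and the chemokine receptor list (-0.28, adjusted p = 0.023) passed camera as well at the preset correlation. With an estimated correlation camera gave them adjusted p of 0.673, 0.502 and 0.51. The MHC class II list passed only with all 4 samples or without CCR2+/- sample 2. Its median had the other sign with a sample left out and with the authors' clusters. The chemokine receptor list missed the threshold without CCR2+/- sample 2 and without CCR2-/- sample 1. Hba-a1, a haemoglobin chain of red cells, rose by 2.60 (adjusted p = 0.000253). It was 1.51 without CCR2+/- sample 1 and 3.69 without CCR2+/- sample 2, and the 4 haemoglobin genes had a median of 2.49.

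**Figure D1:**
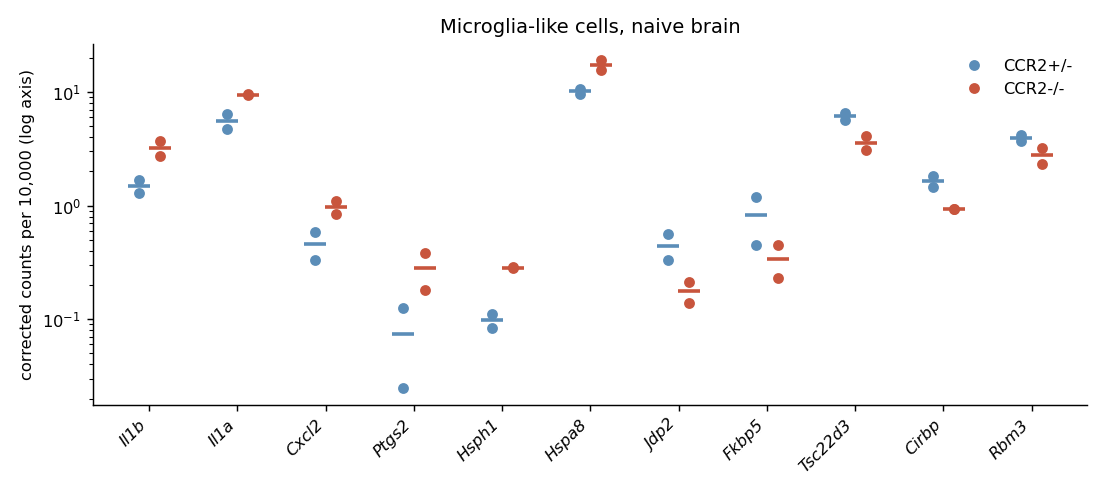
Levels of 11 genes in microglia-like cells, in corrected counts per 10000 on a log axis, with a point for each hashed sample and a dash for the mean of CCR2+/- and of CCR2-/- samples. Il1b lies at 1.28 and 1.67 in CCR2+/- and at 3.71 and 2.75 in CCR2-/- samples.

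In endothelial cells, which line the vessels, few genes were called, and the lists of interferon and antigen-presentation genes were mostly higher in CCR2-/- brains without passing when the correlation between genes was estimated. Limma called 5 genes that rose and 0 that fell among 7784 tested, with 389 genes at an unadjusted p under 0.05, as many as chance alone gives. The 5 genes, named after their values were seen, were the interferon-induced GTPases Gbp4 (log2 2.41, adjusted p = 0.0307) and Igtp (3.00, adjusted p = 0.0461), the non-classical MHC class I genes H2-Q6 (2.19, adjusted p = 0.0439) and H2-Q7 (2.27, adjusted p = 0.0439), and the chemokine scavenger Ackr1 of venules (2.58, adjusted p = 0.0439). Each was higher in both CCR2-/- samples than in both CCR2+/- samples. Without CCR2-/- sample 1 none of them passed, at 2.06 for Gbp4, 2.21 for Igtp, 1.86 for H2-Q6, 1.73 for H2-Q7 and 2.88 for Ackr1, and Ackr1 also missed the threshold without CCR2-/- sample 2, at 2.27. The count of called genes was 37 without CCR2+/- sample 1, 93 without CCR2+/- sample 2, 0 without CCR2-/- sample 1 and 19 without CCR2-/- sample 2. The samples held 68 and 41 CCR2+/- and 38 and 51 CCR2-/- endothelial cells. This class joined 2 clusters, and its mix differed between samples. The cluster with Cldn5 and Slco1a4 among its top genes held 38 and 8 CCR2+/- cells and 11 and 20 CCR2-/- cells. Whether this mix moved the values of the class was not tested.

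The interferon response list in endothelial cells had a median log2 difference of 1.13, with 19 members higher and 1 lower, and between 0.92 and 1.28 without any 1 sample. Over all genes tested 0 of its members passed limma, and adjusted over the list alone 14 rose; camera gave adjusted p = 8.36e-24 at the preset correlation. MHC class I genes, which display peptides to CD8 T cells, had a median of 1.00, with all 10 members higher, 1 passing over all genes and 10 adjusted over the list alone (camera adjusted p = 3.23e-22). Their median was 0.63 without CCR2-/- sample 1. MHC class II genes, which display peptides to CD4 T cells, had a median of 2.24, with all 6 members higher, 0 passing over all genes and 4 adjusted over the list alone (camera adjusted p = 5.26e-09). Their median was 0.90 without CCR2-/- sample 1 and 3.58 without CCR2-/- sample 2. The interferon gamma list had a median of 1.90, with all 6 members higher, 1 passing over all genes and 4 adjusted over the list alone (camera adjusted p = 2.36e-12). With an estimated correlation each of these lists had adjusted p = 0.522. Lists that sample handling can move differed in the same cells at the preset correlation. The heat shock list had a median of 0.54 (7 higher, 1 lower, camera adjusted p = 0.000196). The dissociation and immediate early list had -0.27 (1 higher, 17 lower, camera adjusted p = 0.000266) and missed the threshold without CCR2-/- sample 2, at -0.23. With an estimated correlation camera gave adjusted p = 0.522 for both of these lists. Whether these differences in endothelial cells differ from those in microglia was not tested. In pericytes and fibroblasts limma called 0 of 6256 genes, with 643 at an unadjusted p under 0.05, and 220, 0, 88 and 30 genes without CCR2+/- samples 1 and 2 and CCR2-/- samples 1 and 2. The median of all genes there was -0.41, and 15 lists passed camera at the preset correlation. Among them the interferon list had a median of -1.497 (camera adjusted p = 0.0202), which missed the threshold without CCR2+/- sample 2, at -0.85, and had the other sign after thinning, at 0.46. This class joined 2 clusters and its mix and depth differed: the smaller cluster held 16 of 60 and 16 of 25 CCR2+/- cells and 7 of 40 and 5 of 24 CCR2-/- cells, and the median depths were 6383 and 2412 UMIs.

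In blood, Cx3cr1 RNA was lower in Hom than in Het monocytes of naive and of metastasis-bearing mice, while Ccr2 RNA was near its Het level. Ly6c-low monocytes patrol the vessel wall and depend on Cx3cr1 for survival. In naive Ly6c-low monocytes Cx3cr1 was 4.45 per 10000 in Het and 0.52 in Hom (log2 -3.01), found in 70 of 80 cells (87.5%) and 12 of 57 cells (21.1%), at median depths of 8615 and 9171 UMIs. In metastasis-bearing mice it was 3.15 and 0.378 (log2 -3.01), found in 76.4% of 123 and 17.3% of 127 cells, at 11909 and 11375 UMIs. In Ly6c-high monocytes it was 2.00 and 0.424 in naive mice (60.2% and 19.1% of cells, at 12075 and 12570 UMIs) and 1.60 and 0.23 in metastasis-bearing mice (47.5% and 8.95%, at 13873 and 15065 UMIs). B cells, which lack Cx3cr1, showed a background of 11.4% and 12% in naive mice, at 4476 and 4618 UMIs, and of 10.0% and 8.97% in metastasis-bearing mice, at 4107 and 4029 UMIs. Thinned to equal depth, the shares in Ly6c-low monocytes were 36.2% and 7.02% in naive mice and 24.4% and 1.57% in metastasis-bearing mice. The EGFP transcript, a green fluorescent reporter, was found in 7.95% of Het and 27.7% of Hom naive Ly6c-high monocytes and in 13.8% and 22.8% of naive Ly6c-low monocytes. It was found in 0 of 465 Het and 0 of 881 Hom naive B cells, which allows shares of up to 0.645% and 0.341%. Ccr2 in Ly6c-high monocytes was 19.8 and 19.2 per 10000 in naive and 23.9 and 19.2 in metastasis-bearing mice. RFP was found in 0 of 88 Het and 0 of 94 Hom naive Ly6c-high monocytes, which allows shares of up to 3.41% and 3.19%. In metastasis-bearing mice it was found in 1 of 179 Het and 0 of 324 Hom cells of this class. These values give no ground to read blood Het and Hom as the CCR2+/- and CCR2-/- of the brain.

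**Figure D2:**
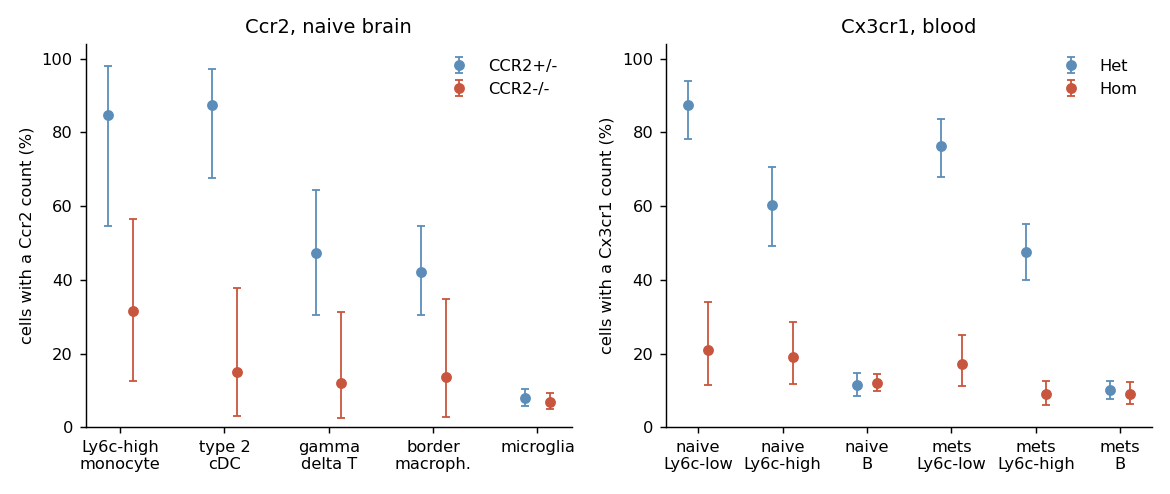
Percent of cells with a Ccr2 count in classes of naive brain (CCR2+/- and CCR2-/-) and with a Cx3cr1 count in classes of blood (Het and Hom), with exact 95% Clopper-Pearson intervals as bars. In naive Ly6c-low monocytes Cx3cr1 lies at 87.5% in Het and 21.1% in Hom.

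The comparison of naive Het and Hom blood asked which circulating cells differ by genotype before tumour cells are given. The naive Hom blood held more B cells and fewer neutrophils than the naive Het blood. B cells were 27.1% (95% interval 25 to 29.3) of Het and 44.5% (42.3 to 46.8) of Hom cells, and neutrophils 41.2% (38.9 to 43.6) and 15.4% (13.9 to 17.1). T cells were 7.69% and 13.7%, NK cells 0.641% and 3.19%, and Ly6c-high monocytes 5.13% and 4.75%. With 1 sample per group there was no measure of the spread between mice, and these main results of blood were chosen after their values were seen.

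Naive Hom neutrophils had less Steap4, Acod1 and Lcn2 RNA and more MHC class I and apoptosis RNA than Het neutrophils. The median log2 ratio of all genes in this class was 0.22, which was not subtracted from the values. Steap4, a metalloreductase induced by inflammation, was 3.00 per 10000 in Het and 0.64 in Hom neutrophils (log2 -2.21). Acod1, which makes itaconate in activated myeloid cells, was 1.40 and 0.22 (log2 -2.63), and Lcn2, an iron-siderophore binder, 26.8 and 11.1 (log2 -1.27). Plscr1, an interferon-induced scramblase, had a log2 ratio of -2.78 and Isg15, an interferon-induced ubiquitin-like protein, -0.89. The interferon response list had a median of -0.55, with 3 members higher and 19 lower, below all of its matched random lists. An unnamed cluster nearest to neutrophils, with interferon-induced top genes, was not part of the class and held 12 Het and 21 Hom cells. With it the list's median was -0.09 and Isg15 had -0.31, and with the authors' clusters the median was -0.16, so a difference in interferon-induced RNA was not settled. Ptgs2 was higher in Hom (2.21 against 0.72, log2 1.61), as were H2-Q7 (1.68), H2-K1, a classical MHC class I gene (1.03), Cxcr4, the receptor that returns aged neutrophils to marrow (0.82), Cd274, the checkpoint ligand PD-L1 (1.31), and Pmaip1, a promoter of apoptosis (1.32). MHC class I genes had a median of 0.41 (9 higher, 1 lower) and apoptosis genes 0.75 (7 higher, 2 lower). Of the cluster that held most Het neutrophils, 604 cells were Het and 11 Hom.

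Naive Hom Ly6c-high monocytes had more MHC class II RNA in sum, part of it in cells with a dendritic cell marker. The list had a median of 1.20, with all 7 members higher, Cd74, the invariant chain of MHC class II, was 11.6 per 10000 in Het and 23.2 in Hom (log2 1.00), and H2-Aa had a log2 ratio of 1.20. Few cells carried it: H2-Aa was found in 16 of 88 Het and 20 of 94 Hom cells, and 1 cell held 26.1% of the list's counts in Het and 1 cell 12.4% in Hom. Without these 2 cells the median was 1.30. Cd209a, a marker of type 2 dendritic cells, was higher too (log2 3.30), found in 2 of 88 Het and 11 of 94 Hom cells, and these Hom cells held 33.2% of the list's Hom counts. Without the cells with a Cd209a count the median was 0.62. Cxcl10 was higher (log2 3.52), with counts in 4 of 88 Het and 7 of 94 Hom cells, and 1 Hom cell held 33.8% of the Hom counts. S100a8, an alarmin of neutrophils and young monocytes, was lower (log2 -3.69), with 35.8% of the Het counts in 1 cell, and -3.44 without the top cell of each sample. The neutrophil gene Retnlg was lower as well (log2 -4.53), found in 4 of 88 Het and 2 of 94 Hom cells. In naive B cells the MHC class I list had a median of 0.15 (8 higher, 2 lower).

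The comparison of Het and Hom blood in metastasis-bearing mice asked which circulating cells differ by genotype in the presence of brain tumours. In these mice the Hom blood held fewer B cells and more Ly6c-high monocytes than the Het blood. B cells were 31.8% (29.8 to 33.8) of Het and 18.9% (17.2 to 20.7) of Hom cells, and Ly6c-high monocytes 8.63% (7.46 to 9.92) and 16.7% (15 to 18.4). Neutrophils were 36.2% of both, or 2.91 percentage points higher in Hom with an unnamed cluster of interferon-induced genes nearest to neutrophils, and T cells 6.61% and 6.74%.

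Hom neutrophils of metastasis-bearing mice had more interferon-induced RNA and less granule RNA than Het neutrophils. Steap4 was 0.53 in Het and 2.22 in Hom (log2 2.06). Ifi27l2a, an interferon-induced mitochondrial protein, was 3.73 and 7.97 (log2 1.09), Npl, a sialic acid lyase, had a ratio of 1.77 and Stfa2, a cysteine protease inhibitor of neutrophils, 1.37. Chil3, a chitinase-like protein of young myeloid cells, had a ratio of -1.06, Mmp8, a granule collagenase, -0.71, and Lcn2 -0.61 (29.0 and 18.9). The interferon list had a median of 0.36, with 19 members higher and 1 lower, and the granule list -0.22. An unnamed cluster with interferon-induced top genes held 47 Het and 101 Hom cells, and with it the interferon median was 0.61. In Ly6c-low monocytes the interferon list had a median of 0.29 (19 higher, 3 lower) and the MHC class II list -0.66 (0 higher, 9 lower). In B cells the interferon list had a median of 0.43 (16 higher, 5 lower), with Ifit3, an interferon-induced antiviral gene, at 1.97, and S100a6, a calcium-binding protein of memory B cells, at 1.23. A B cell cluster with Bhlhe41 among its top genes held 32 of 659 Het and 51 of 368 Hom B cells, and without it S100a6 was at 0.13.

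Hom Ly6c-high monocytes of metastasis-bearing mice had more Wfdc21, Lrg1 and F11r RNA and less immediate early RNA. Wfdc21, a neutrophil protease inhibitor, had a log2 ratio of 3.099, Lrg1, an acute phase glycoprotein, 2.64, and F11r, a junction adhesion molecule, 2.12. S100a8 was 1.38 and its partner S100a9 1.63 higher on the log2 scale, but with the authors' clusters they were -0.92 and -1.12, so their direction was not settled. Jun, an AP-1 subunit induced within minutes, had a ratio of -1.24. The immediate early list had a median of -0.44 (3 higher, 13 lower) and the inflammatory list -0.58 (2 higher, 8 lower); without the cell of each sample with most MHC class II counts these were -0.28 and -0.17. Cxcl10 had a ratio of -3.25, but 1 Het cell held 69.6% of the Het counts.

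**Figure D3:**
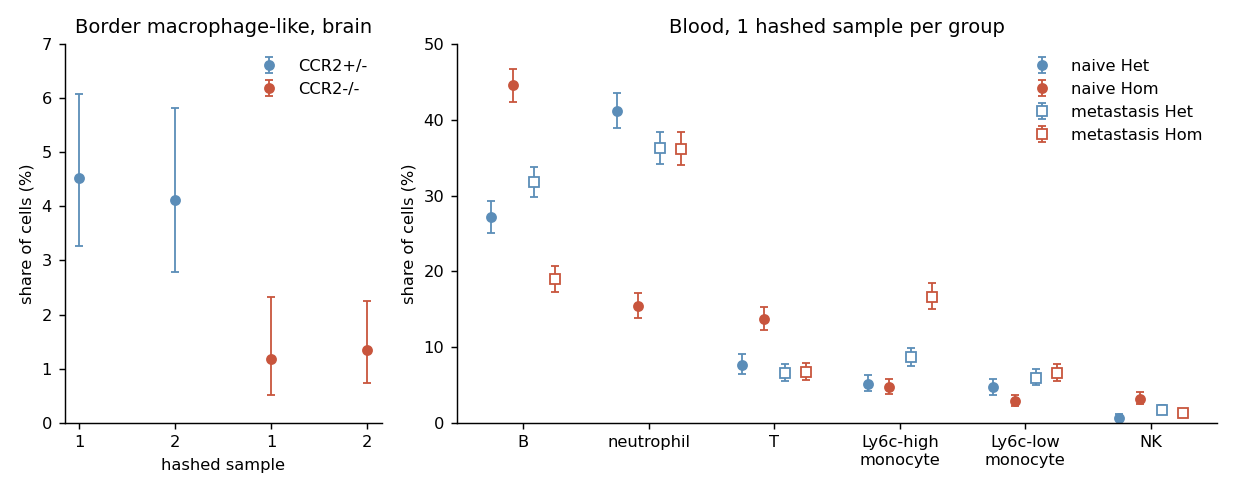
Percent of border-associated macrophages in each naive brain sample and of 6 classes in each blood sample, with exact 95% Clopper-Pearson intervals as bars. B cells lie at 27.1% and 44.5% in naive Het and Hom and at 31.8% and 18.9% in metastasis-bearing Het and Hom blood.

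The comparison of metastasis-bearing with naive blood of the same genotype asked what a growing brain tumour changes in the circulation. Among neutrophils of metastasis-bearing mice a small cluster carried granule RNA of young neutrophils. Camp, an antimicrobial granule peptide, had log2 ratios of 4.31 in Het and 4.73 in Hom, and Ngp, a granule protein of marrow neutrophils, 2.90 and 3.64. Ltf, the granule protein lactoferrin, had 4.10 in Het. The granule list had medians of 0.47 and 0.67, against medians of all genes of 0.22 and -0.01. The cluster with Camp and Ngp among its top genes held 8 of 751 Het and 9 of 704 Hom neutrophils. Without it Camp had ratios of -0.21 and 0.30, Ngp -0.20 and 0.58, Ltf -0.62 in Het, and the granule list -0.11 and 0.30. The interferon list in neutrophils had a median of -1.54 in Het (1 higher, 21 lower) and -0.75 in Hom (6 higher, 14 lower), but in Hom it was 0.21 at a higher clustering resolution. Steap4 was lower in Het (log2 -2.49) and higher in Hom (1.78). Isg15 and Ifit1, another interferon-induced antiviral gene, had ratios of -2.61 and -3.08 in Het, and H2-Q7 and Ptgs2 ratios of -2.00 and -1.75 in Hom.

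**Figure D4:**
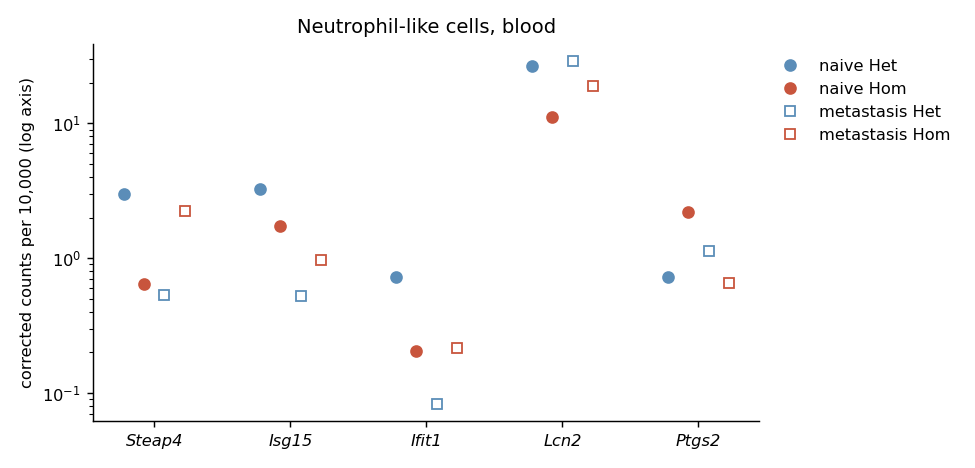
Levels of Steap4, Isg15, Ifit1, Lcn2 and Ptgs2 in neutrophil-like cells of the 4 blood samples, in corrected counts per 10000 on a log axis. Steap4 lies at 3.00 and 0.64 in naive Het and Hom and at 0.53 and 2.22 in metastasis-bearing Het and Hom blood.

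Ly6c-high monocytes of metastasis-bearing mice had less interferon-induced RNA than naive ones in both genotypes. The interferon list had medians of -0.99 in Het and -1.09 in Hom, with 0 higher and 23 lower in each, against medians of all genes of -0.20 and -0.17. Chil3 had log2 ratios of 2.26 in Het and 1.09 in Hom, Vcan, the matrix proteoglycan versican, 1.77 in Het, and Lcn2 4.38 in Hom. The MHC class II list had medians of -3.15 in Het and -4.95 in Hom, with Cd74 at -3.46 and -4.95 and H2-Aa at -3.77 and -7.15. In Het the direction of the MHC class II list depended on how monocytes were divided: it was 0.44 at a lower and 0.28 at a higher clustering resolution, and 0.15 with both monocyte classes as 1 class. In Hom it was -1.13 with the authors' clusters and -1.75 with both classes together. In Ly6c-low monocytes the alarmin list had medians of 1.21 in Het and 1.15 in Hom (10 higher and 2 lower in each), against medians of all genes of -0.13 and -0.14. Its size depended on the clustering: the medians were 0.28 and 0.51 at a lower and 0.69 and 0.62 at a higher resolution. Ccr2, a marker of Ly6c-high monocytes, went with it, from 3.79 to 9.83 per 10000 in Het and from 3.09 to 7.86 in Hom, and the metastasis-bearing cluster also scored 2.00 for Ly6c-high monocytes, against 0.637 for the naive cluster.

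B cells of metastasis-bearing mice had more S100a6 than naive B cells, with log2 ratios of 1.48 in Het and 2.62 in Hom. The cluster with Bhlhe41 was named in metastasis-bearing but not in naive mice; with the unnamed naive cluster (23 Het and 40 Hom cells) the ratios were 0.46 and 1.45, and without the named one 0.69 and 0.72. In Het B cells the interferon list had a median of -0.54 (4 higher, 18 lower) and the heat shock list -0.57. In T cells Txnip, a thioredoxin inhibitor, and Rbm3 each had a ratio of 1.17 in Het, and S100a4, a calcium-binding protein of effector cells, 2.30 in Hom. B cells took 31.8% of metastasis-bearing and 27.1% of naive Het cells but 18.9% and 44.5% of Hom cells. Neutrophils took 36.2% and 41.2% of Het and 36.2% and 15.4% of Hom cells, and Ly6c-high monocytes 8.63% and 5.13% of Het and 16.7% and 4.75% of Hom cells.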

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

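The tests of hashtag counts, EGFP and RFP in brain-table cells and the test of genotype alone in neutrophils were chosen after their results had been seen; the other tests were chosen before.

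Several differences between Hom and Het blood went opposite ways in naive and metastasis-bearing mice; with 1 sample per group these contrasts were not tested. The share of B cells was 17.4 percentage points higher in naive Hom blood and 12.9 points lower in metastasis-bearing Hom blood (-12.9), so the genotype differences lay -30.3 points apart. In neutrophils the interferon response list had medians of -0.55 and 0.36, which differ by 0.915, and Steap4 had log2 ratios of -2.21 and 2.06, which differ by 4.27. The lipid handling list (-0.32 and 0.24) differed by 0.557. The haemoglobin list (-1.14 and 0.55) differed by 1.69, but 1 naive Het cell held 35.4% and 1 metastasis-bearing Hom cell 23.7% of its counts, and without the top cell of each sample it was -0.50 and 0.09. Its direction also turned with the authors' clusters in naive mice and with all deposited cells in metastasis-bearing mice. With the unnamed clusters of interferon-induced neutrophils the interferon medians were -0.09 and 0.61.

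Naive Het and Hom neutrophils lay mostly in different clusters, with 604 Het and 11 Hom cells in the cluster that held most Het neutrophils. A difference in depth was not settled by thinning. With each cell thinned to the same number of counts, the median signed log2 ratio of the 51 named genes was 1.03 times its value at full depth. The thinned values had already been corrected for depth. Thinning at random does not move a ratio on average, so this could not decide. The median depths of these neutrophils were 3141 UMIs in Het and 2953 in Hom. The same genes had a median signed log2 ratio of -0.081 between the samples of metastasis-bearing mice, where 19 of 51 kept their sign. These genes thus did not differ in a like way by genotype there. With 1 sample per group this cannot exclude genotype as the cause. An effect of genotype that holds only in naive mice was not tested. A difference between the single mice or in the handling of their blood also stays open.

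In CCR2-/- microglia 3 heat shock and 3 inflammatory list members rose over all genes tested, while Cirbp and Rbm3 fell. Neither list passed camera with an estimated correlation. Another mix of the 2 microglia clusters was argued against: within each of them the called genes had at least 0.848 of their median log2 difference over the whole class. This covers the called genes as a set and only these 2 clusters. At a higher resolution 1 microglia cluster of 249 cells had Tnf, Ccl3, Ccl4 and Il1a among its top genes. A different share of such smaller groups was not tested and stays open. A difference in how the whole brain samples were handled remains a candidate explanation, because the heat shock list had a median of 0.539 in endothelial cells too. In those cells the mean of Cirbp and Rbm3 was -1.45. The mix of the 2 endothelial clusters differed between samples, and its part in these endothelial values was not tested. Free red-cell RNA was left undecided. The called genes other than haemoglobin had a median signed difference of 0.336 in endothelial cells against 0.591 in microglia. Of these, 40 of 52 had the same sign. The haemoglobin genes, which this explanation needs to be higher in both classes, went the other way in endothelial cells (-3.39 against 2.49). All samples shared 1 pool, so free RNA of the pool would reach cells of both genotypes. Loss of CCR2 itself stays open and was not tested apart from handling.

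In the naive brain table, 1261 of 1393 neutrophils, B cells, Ly6c-high monocytes and T cells (90.5%) lacked a clear brain hashtag and were not used in the comparisons, against 117 of 1352 microglia (8.65%). Weak hashtag staining of leukocytes inside the brain tissue was argued against, since RFP was found in 6.90% of 232 unclear Ly6c-high monocytes (interval 3.99 to 11) against 53.1% of the 32 clear ones (lower bound 34.7). Cells of the pooled blood samples remain a candidate explanation. Of the 1261, 1195 also stood in a blood table, but this is no support, since standing there made a cell unclear by itself. Of these 1195, 94.9% (interval 93.5 to 96.1) had more counts on that table's hashtags than on the brain hashtags. This share was not set by that rule, as it was 30.4% among the 115 unclear microglia that also stood in a blood table. In monocytes EGFP alone did not decide. It was found in 12.5% of the unclear ones (interval 8.53 to 17.5) and in 0 of 32 clear ones, with an upper bound of 10.9. Of the clear brain microglia, 1 of 589 CCR2+/- and 0 of 646 CCR2-/- cells had an EGFP count. In naive blood it was found in 7.95% of Het and 27.7% of Hom Ly6c-high monocytes, so the unclear monocytes lay within the blood range. No biological explanation was tested.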

How the results depend on the processing

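In all, 180 values were recomputed under 3211 alternatives, of which 31 were counted as reversed. They were counts of called genes, differences of genes and lists, and shares of cells per class. Ccr2 levels of brain classes that were not fitted with limma were not among them. The shares of cells with a Ccr2, Cx3cr1, EGFP or RFP count were not among them either. A change of sign was counted only where the value passed the threshold in either fit or lay outside its spread. Counts of genes have no direction. The other 3180 alternatives therefore include changes of sign in values near 0, such as the microglia share. Of the 24 main results, 315 of 367 alternatives stayed within the spread or on the same side of the threshold, 47 moved and 5 reversed; of the other 156, 2465 of 2844 were unchanged in this sense, 107 lost and 19 gained a call, 227 moved and 26 reversed. All deposited cells, stricter hashtag assignment, the authors' clusters, both monocyte classes together, leaving out the highest doublet scores, and clusters, top cells or carriers of a gene added to or left out of a blood class were chosen after seeing the data. Where a brain sample was left out, its lone partner was assumed to vary like the other group. The count of called microglia genes was 28 to 128 with a sample left out, and 5 after thinning, which leaves fewer counts per gene. For the other changes the cause was not tested. Values are log2 unless said otherwise. In microglia, with a sample left out, the homeostatic list was -0.028 to 0.028 and the MHC class II list -0.042 to 0.321; the latter was also -0.042 with the authors' clusters. The interferon gamma list was -0.067 after thinning. In pericytes the interferon list was 0.462 after thinning, and the MHC class I list -0.069 without the highest doublet scores and -0.054 at lower resolution. With all deposited cells, Cx3cr1 in Ly6c-low monocytes was -1.791 in naive and -2.441 in metastasis-bearing mice, and Steap4 was -2.21 in Het between disease states (metastasis-bearing against naive). After thinning, Steap4 was -1.709 in naive mice, 1.759 in metastasis-bearing mice, and -2.186 in Het and 1.283 in Hom between disease states. The interferon list in naive neutrophils was -0.323 after thinning, -0.163 at lower resolution, -0.16 with the authors' clusters and -0.282 with a pseudocount of 10, which also put the granule list at 0.167; with the unnamed cluster of interferon-induced genes it was -0.087. In metastasis-bearing mice it was 0.606 at lower and 0.603 at higher resolution, 0.6 with the authors' clusters and 0.606 with that unnamed cluster. Between disease states it was, in Het, -1.187 at lower and -0.991 at higher resolution, -1.183 with the authors' clusters, -1.254 with the unnamed clusters and -1.74 with median-of-ratios scaling, and in Hom -0.476, 0.212 and -0.471 for the first 3 of these and -0.536 with all deposited cells. The haemoglobin list in neutrophils was 0.021 with the authors' clusters in naive and -2.277 with all deposited cells in metastasis-bearing mice. Without the cluster with Camp and Ngp, the Het difference between disease states was -0.212 for Camp, -0.201 for Ngp, -0.62 for Ltf and -0.107 for the granule list, since that cluster held most of these counts. In metastasis-bearing Ly6c-high monocytes S100a8 was -0.916 with the authors' clusters and -0.766 with both monocyte classes together, and S100a9 was -1.118 and -0.972, and -0.166 with all deposited cells. Between disease states in Het monocytes, lower resolution, higher resolution and the authors' clusters gave 0.436, 0.275 and 0.245 for the MHC class II list, 0.436, 0.275 and 0.148 for Cd74, and 0.787, 0.623 and 0.579 for H2-Aa. Both monocyte classes together gave 0.151 for the list and 0.258 for H2-Aa, a pseudocount of 10 gave -2.717 for the list, no count filter -2.639, and leaving out the cell of each sample with most of these counts -3.633. In Hom the list was -1.735, -1.833 and -1.127 under the first 3, -1.751 with both classes together, -4.616 without cells with a Cd209a count, -5.475 with a minimum of 50 counts and -4.052 with no count filter. The border macrophage difference, in percentage points, was -3.479 for cells with 1000 or more UMIs, -2.379 with all deposited cells, -3.598 with stricter hashtags and -3.534 without non-immune cells. It had no value at lower resolution or with the authors' clusters, where no cluster took that name. With all deposited cells the naive neutrophil difference was -21.97 points and the B cell difference between disease states 7.67 in Het and -18.361 in Hom; the Het neutrophil difference was -9.155 at higher resolution and the Hom one 24.907 with the unnamed clusters of interferon-induced genes. DESeq2, edgeR and the trimmed mean of M values were not run because the tables hold no raw counts. Leaving out cells with markers of another class was not run. Depth limits the single genes called in microglia, as the thinned count shows.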

Other observations

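All values in this part were chosen after they had been seen.

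Barcodes were shared between the tables: 926 stood in the brain and naive blood tables, 970 in the brain and metastasis-bearing blood tables, 845 in both blood tables, and 170 in all 3. Of the 5208 cells of the brain table, 1726 (33.1%) also stood in a blood table. Within the brain table the share of cells without a clear brain hashtag was 92.9% of B cells, 91.1% of neutrophils, 87.9% of Ly6c-high monocytes and 84.9% of T cells, against 35.8% of NK cells and 19.8% of border macrophages.

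The authors' antibody gates and the RNA classes also differed in metastasis-bearing blood. The NK gate held 325 Het cells, of which 41.5% had Ly6c-high monocyte RNA, 27.1% Ly6c-low monocyte RNA and 9.85% NK cell RNA. The Ly6C-high gate held 58 Het and 420 Hom cells, and the NK gate held 14 Hom cells.

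Haemoglobin RNA differed between brain samples in opposite ways by class. In microglia the 4 haemoglobin genes rose in CCR2-/- samples, with a median log2 difference of 2.49, and in endothelial cells they had a median of -3.39 (limma's camera adjusted p = 0.00095 at the preset correlation, adjusted p = 0.522 with an estimated correlation). The homeostatic microglia list had a median of 1.25 in pericytes and fibroblasts (12 members higher and 2 lower), a class that should not express it.

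In the CCR2-/- brain, RFP was found in 8 of 19 Ly6c-high monocytes (42.1%). In metastasis-bearing blood EGFP was found in 12.2% of Het and 22.0% of Hom Ly6c-low monocytes and in 8.38% and 9.26% of Ly6c-high monocytes, against 0 of 659 and 0 of 368 B cells, which allows up to 0.455% and 0.815%.

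T cells of naive Hom blood had less MHC class II RNA than those of naive Het blood, with a median log2 ratio of -1.14 and 0 of 8 members higher. A T cell cluster that resembled B cells as its second class held 19 of 132 Het and 16 of 271 Hom T cells, and without it the median was -1.58. In Hom T cells of metastasis-bearing against naive mice the activation and exhaustion list had a median of 0.62, with 6 members higher and 1 lower.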
